A study of Mus musculus with 10 samples.

How the data were processed

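Expression was measured in cells isolated as liver sinusoidal endothelial cells from female C57BL/6N mice on 10 Affymetrix arrays, 5 per diet. Per the labels' protocols, livers were perfused and digested with collagenase, cells of 3 mice were pooled for each array, the non-parenchymal fraction was taken from a density gradient, and cells were bound to magnetic beads against CD146. Biotin-labelled cRNA was hybridised. The deposited log2 values were made by the authors with robust multi-array average (RMA), per the submitters' processing notes, with no version given in the sources used here. RMA subtracts a background, brings all arrays to one distribution and summarises the probes of each probe set. The sorted values of the 10 arrays agreed within 0.00186, and no 2 arrays shared more than 0.244% identical values. CDAA 1 held 24921 distinct values and every other array 10080, so the values of CDAA 1 were given in finer steps. The reason is not known here. Pearson correlations across probe sets, which are not independent replicates, were 0.972 to 0.991 within CDAA, 0.980 to 0.992 within Std and 0.947 to 0.982 between diets. Background correction could not be varied, since scanner files are not used here. Neither array design, genome build nor dates are given in the sources used here, so no coordinates are printed and no batch could be set up. For arrays, their number limits the precision.

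Probe sets were named from the platform annotation: of 25428, 24705 had 1 gene symbol, 0 had several and 723 had none and are unnamed here. 1 gene had 2 or more probe sets, of which the one with the highest mean over all arrays was kept, giving 24704 genes. CDAA was compared with Std with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. A change is the CDAA minus Std difference in log2 value. "Rose" and "fell" are used of genes past the threshold. The replicates are separate pools, so p-values measure the spread between pools and not between single mice.

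The 34 gene lists, with 490 entries of which 25 had no named probe set here, were fixed before the data were examined, as were the groups, the tests, the first set of other fits and the rule for named genes. The 33 lists with at least 5 measured genes were tested with camera of limma at its preset inter-gene correlation of 0.01, adjusted over the lists. Camera was repeated with an estimated correlation, and fry of limma was run. Counts within a list are given over all genes and after adjustment over the list alone. Some list genes are expressed by more than 1 cell type of the liver, so a list is not a measure of cell number.

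By the rule, the text names the 8 largest rises and 8 largest falls among genes past the threshold whose arrays did not overlap between diets (predicted, microRNA and small nucleolar RNA genes left out). It adds Gata4, Pdgfb, Myc, Lyve1, Stab2, Cd34, Emcn, Wnt2, Wnt9b, Rspo3, Bmp2 and Mcam whatever their value. It also takes up to 3 members per list with the largest change past the threshold, or the one with the smallest p where none passed. That made 105 genes, some of which enter only the counts of named genes. A further 37 were chosen after their values were seen: Ccr2, Cx3cr1, Clec4f, Vsig4, C1qa, C1qb, C1qc, Sox9, Pdgfrb, Acta2, Col4a1, Col4a2, Jag1, Ccnd2, Igf1, Igfbp5, H2-K1, B2m, Vcam1, Mylip, Mcm3, Cyp2e1, Ass1, Smad6, Smad7, Igha, Igkc, Cldn3, Cldn4, Cldn5, Ctss, Sema3c, Sema3d, Pcdhga10, Pcdhgb5, Ms4a7 and Gata6.

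The first set of other fits used the replicate number as a block, quantile normalization again, centring on array medians, leaving out the dimmest 25% of genes or those below the median, an intensity trend with robust variance, array weights, the mean of a gene's probe sets, the hepatocyte or the Kupffer cell marker mean as a covariate, a test against a log2 change of 0.5 (treat) and leaving out each array in turn. Added after seeing the data were fits without CDAA 1 and CDAA 3, without these and Std 3, and with the pan-endothelial or the neutrophil marker mean as a covariate. Values of single quantities were compared with two-sided exact permutation tests over all 252 arrangements, whose smallest p is 0.00794. For counts of genes and lists, 100 splits of the arrays into 5 and 5 were drawn. An array was called far from its group when its gap to the nearest other array exceeded 0.71 of the group's range (Dixon's value for 5 arrays). The added lists (a second neutrophil list, pancreatic acinar genes and general macrophage genes) and 10 gene families were chosen after seeing the data.

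The limma procedure was tested on simulated data with 200 of 24704 genes changed. Noise was drawn for each gene independently, with that gene's residual SD from the arrays, equal in both diets. The procedure recovered 17% of changes of 0.5 on the log2 scale with 1 false call, 86.5% of changes of 1 with 13 false calls, and 99% of changes of 2 with 5 false calls. Noise shared between genes, spreads that differ between diets and a number of changed genes near the 4106 called here were not simulated. These rates therefore need not hold for the real comparison. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.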

Results

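Gene expression was measured on 10 Affymetrix arrays in cells isolated as liver sinusoidal endothelial cells (LSEC), the fenestrated cells that line the capillary-like sinusoids of the liver. The cells came from female C57BL/6N mice that were 10 weeks old when feeding began. Mice received either a CDAA diet, in which fat gave 31% of calories and cholesterol made up 1%, or a control diet (labelled Std), for 10 weeks. In liver research CDAA usually stands for a choline-deficient, amino acid-defined diet, which is used to induce fatty liver with fibrosis. Each array carried RNA of cells pooled from 3 mice and selected with magnetic beads against CD146, the product of Mcam. There were 5 pools per diet, named CDAA 1 to CDAA 5 and Std 1 to Std 5, which the labels call biological replicates. A field for treatment duration gives 10 days, whereas titles, descriptions and growth protocol give 10 weeks, and the latter is used here. The series' design text describes mice lacking Gata4 in these cells, but no sample carries that label, and such mice are not analysed here. The values were log2 signals from 25428 probe sets, with the same median of 3.89 on every array. No detection call is used here, so signals below that median were not known to lie above background, and differences from them are differences in signal that can understate the change in transcript. This applied, for example, to Gpnmb, Atp6v0d2, Igkv1-88, Jchain, Timp1 and Ccr2 with Std and to Cd163 and Gbp2b with CDAA.

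The question was which genes the diet changed in the endothelial isolate. With the control diet the isolate already held signal of markers of other cells. Mean log2 values in Std were 9.33 for the Kupffer cell and macrophage list and 7.06 for the hepatocyte list. Changes are thus those of the isolate and not of LSEC alone. Genes typical of recruited, lipid-laden macrophages, of bile duct epithelium and of matrix-producing mesenchymal cells were higher in all 5 CDAA pools, and genes that mark LSEC were lower, as were 4 of 11 Kupffer cell and macrophage markers. The sharpest rise was that of Gpnmb (probe set 93695_at), a transmembrane glycoprotein of lipid-laden macrophages. Its log2 value was 10.76 ± 0.69 (SD, n = 5) with CDAA and 3.45 ± 0.32 (SD, n = 5) with the control diet, a 158-fold difference in signal. Cxcl13 (55985_at), a chemokine that attracts B cells, had the sharpest fall, from 8.32 ± 0.53 to 4.18 ± 0.33, 17.6-fold lower. The 8 largest falls also included the complement component C6, which fell by 2.90, the interferon-inducible GTPase Gbp2b, which fell by 2.54, Cntfr, a receptor of ciliary neurotrophic factor, which fell by 2.37, and the purine nucleoside phosphorylase Pnp2, which fell by 2.30. Among 24704 genes, 4106 changed by limma at a Benjamini-Hochberg adjusted p of 0.05 (16.6%), of which 1851 rose and 2255 fell. Rises were larger: 625 genes rose and 256 fell by at least 1 on the log2 scale. The 5 CDAA and 5 Std values did not overlap for 13.9% of genes, against 0.794% by chance. CDAA 1 and CDAA 3 lay farthest from the Std arrays on the component that held 51.1% of the variance. Without both arrays, 2612 genes changed, 1305 rising and 1307 falling. Of 33 gene lists tested with camera at its preset correlation, 12 shifted upward and 4 downward, but no list passed with an estimated correlation. Other splits of the 10 arrays, each of which kept part of the diet difference, called up to 19 lists.

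**Figure D1:**
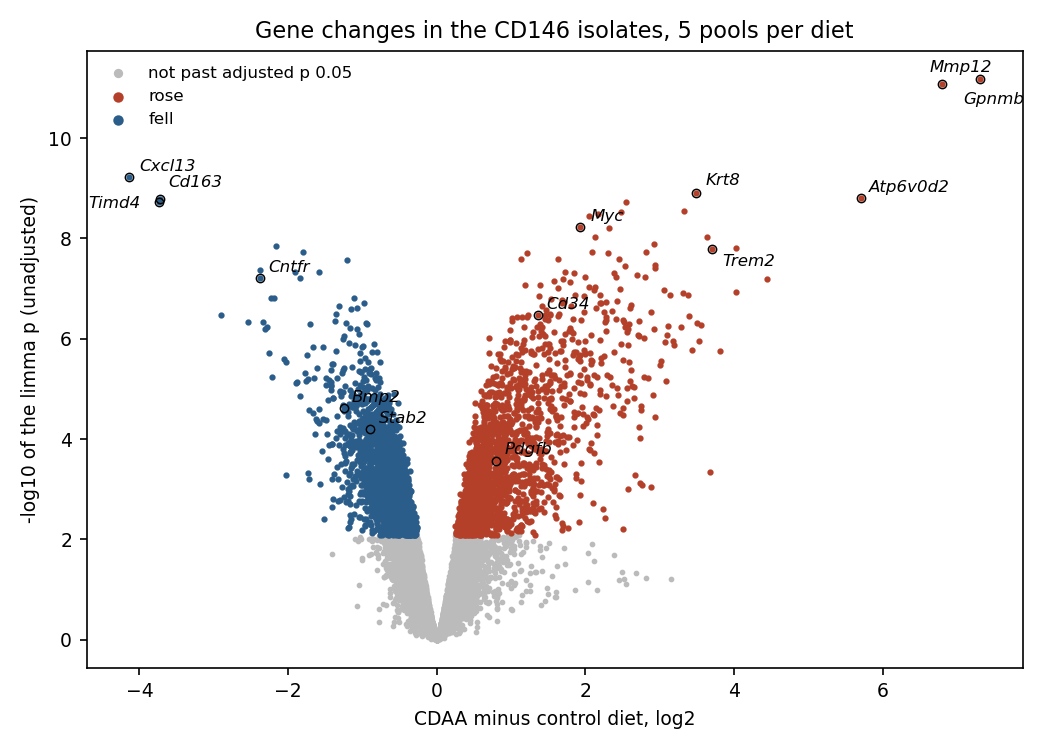
Each point is a gene, with its CDAA minus control log2 difference on the x axis and the -log10 of its unadjusted limma p on the y axis, from 5 pools per diet. The 1851 genes that rose are red, the 2255 that fell are blue and the rest are grey; Gpnmb, Mmp12 and Atp6v0d2 lie farthest to the right, and Cxcl13, Timd4 and Cd163 farthest to the left.

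Macrophage genes were among the largest changes in both directions. Of 12 measured markers of monocytes and recruited macrophages, 8 rose and none fell (9 rose when adjusted over the list alone). Gpnmb rose by 7.31 ± 0.29 on the log2 scale (SE, limma adjusted p = 1.05e-07) and Mmp12, the macrophage elastase, by 6.80 ± 0.27, from 4.33 to 11.12. Itgax, which encodes CD11c, rose by 4.03 ± 0.37, and Trem2, a lipid-sensing receptor of macrophages, by 3.70 ± 0.28 (limma adjusted p = 1.94e-05). The chemokine receptors Ccr2 and Cx3cr1 rose by 2.90 and 2.55. Atp6v0d2, a proton pump subunit of osteoclasts and macrophages, rose by 5.70 ± 0.36, and the chemokine Ccl9 by 4.44 ± 0.38. Camera gave the list an adjusted p of 7.78e-12 with its preset correlation and an adjusted p = 0.140 with an estimated correlation. Some genes of resident macrophages fell. Timd4, a phosphatidylserine receptor of resident Kupffer cells, fell by 3.73 ± 0.24 (limma adjusted p = 5.92e-06), from 7.92 ± 0.34 to 4.18 ± 0.52 (SD, n = 5). Cd163, the haemoglobin-haptoglobin scavenger receptor, which is in none of the fixed macrophage lists, fell by 3.73 ± 0.23, and Marco, Clec4f and Vsig4 fell by 1.88, 1.14 and 1.14. In the Kupffer cell and macrophage list, 4 of 11 measured genes fell and Cd68, a marker of macrophages of any origin, rose by 1.38 ± 0.27 (4 rose and 4 fell when adjusted over the list alone). The complement genes C1qa, C1qb and C1qc differed by 0.79, 0.69 and 0.68 and did not pass, but did without CDAA 4 (0.99, 0.83 and 0.85). That list had a mean change of -0.30 and a median of 0.36, and camera did not call it (adjusted p = 0.793).

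The means of the bile duct and mesenchymal lists were higher in every CDAA pool than in any Std pool. All 8 measured cholangiocyte and progenitor markers rose, also when adjusted over the list alone. The keratins Krt18 and Krt8 rose by 3.64 ± 0.27 and 3.48 ± 0.21 (SE, limma adjusted p = 1.46e-05 and 5.92e-06), the adhesion molecule Epcam by 3.17 ± 0.35 and the transcription factor Sox9 by 2.56. The list mean was 7.52 ± 0.33 in CDAA and 4.69 ± 0.40 in Std (SD, n = 5), with a camera adjusted p of 1.91e-14 and an adjusted p = 0.0622 with an estimated correlation. Tspan8, a tetraspanin of epithelial cells, rose by 4.03 ± 0.31. Among 15 stellate cell and fibroblast markers, 9 rose and none fell (10 rose when adjusted over the list alone). Col1a1 and Col3a1, chains of the fibrillar collagens, rose by 3.43 ± 0.40 and 2.59 ± 0.35, the proteoglycan Lum by 2.50 ± 0.39 and the growth factor receptor Pdgfrb by 1.02. Acta2, the smooth muscle actin of contractile myofibroblasts, differed by 0.50 and did not pass (limma adjusted p = 0.0535); it passed under 8 of 25 other settings, among them without CDAA 3 (0.56) or Std 3 (0.65). Camera gave an adjusted p of 4.78e-08 for this list, and an adjusted p = 0.191 with an estimated correlation. Of 21 extracellular matrix and matrix enzyme genes, 10 rose and 2 fell (12 and 3 when adjusted over the list alone). Fn1, fibronectin, rose by 2.60 ± 0.25, the gelatinase Mmp2 by 1.93 ± 0.27 and the protease inhibitor Timp1 by 1.63 ± 0.13 (limma adjusted p = 2.30e-05), whereas the basement membrane chains Col4a1 and Col4a2 differed by 0.01 and 0.15 and did not pass. The camera adjusted p was 0.000132, with an adjusted p = 0.0622 with an estimated correlation.

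Endothelial genes, and most of all those that distinguish LSEC, were lower with CDAA. In the LSEC identity list, 17 of 20 genes fell (19 when adjusted over the list alone), and the list mean was 10.68 ± 0.42 with CDAA against 11.57 ± 0.05 with Std (SD, n = 5). Stab2, the hyaluronan scavenger receptor of sinusoids, fell by 0.89 ± 0.15 (SE, limma adjusted p = 0.00197), the lectin Cd209b by 2.34 ± 0.24, the membrane trafficking gene Ehd3 by 1.59 ± 0.26 and Bmp2, an iron-regulating ligand, by 1.25 ± 0.19. Gata4, the transcription factor that directs LSEC differentiation, was at 9.58 ± 0.41 with CDAA and 10.10 ± 0.11 with Std, a difference of -0.52 ± 0.17 that did not pass (limma adjusted p = 0.0556). It passed under 7 of 25 other settings, among them without CDAA 2 (-0.59) or CDAA 4 (-0.62), but not without CDAA 1 and CDAA 3 (-0.27). For the hyaluronan receptor Lyve1 the difference was -0.41 ± 0.18, which did not pass (limma adjusted p = 0.157). With the pan-endothelial mean as a covariate the estimates for Gata4 and Lyve1 changed sign, to 0.11 and 0.23, and did not pass. Genes of endothelium in general were lower too: 8 of 12 pan-endothelial markers fell (10 when adjusted over the list alone), with the VEGF receptors Flt1 and Kdr down by 1.34 ± 0.21 and 0.89 ± 0.17. Mcam, the bead target, was at 9.66 ± 0.34 and 9.54 ± 0.10 (limma adjusted p = 0.664), and rose by 0.35 without CDAA 1 and CDAA 3. The pan-endothelial mean was 11.31 ± 0.06 with Std, 10.02 in CDAA 3, 10.43 in CDAA 1 and 10.77 to 11.08 in the other CDAA arrays. Camera adjusted p were 4.89e-12 for the LSEC list (adjusted p = 0.303 with an estimated correlation) and 1.80e-05 for the pan-endothelial list (adjusted p = 0.421 with an estimated correlation).

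With the pan-endothelial mean of each array as a covariate, chosen after seeing the data, 363 genes passed (248 risen, 115 fallen) and 1 of the 20 LSEC genes fell. That covariate moved with the diet. Camera still called the LSEC identity list with it (mean -0.25, adjusted p = 0.000744) but no longer the periportal list, whose mean went from -0.61 to -0.0011 with 0 of 10 genes fallen, nor antigen presentation, from 0.77 to 0.25, nor the pericentral, NRF2 and immediate early response lists. It newly called the capillary endothelium list (0.54), cholesterol synthesis (-0.38) and Kupffer cell and macrophage markers (-0.96). These calls are at the preset correlation, and an estimated correlation, run without covariates only, called no list. Of the 127 named genes that changed, 41 kept their call and direction with it, among them Gpnmb, Mmp12, Trem2, Krt8, Col1a1, Fn1, Myc, Cd34, Ednrb, Cxcl13, Timd4 and Cd163. Another 82, among them Pdgfb, Stab2, Bmp2 and Flt1, did not pass, and the estimates of 4 changed sign without passing.

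Among zonal endothelial genes, 7 of 10 periportal and 4 of 9 pericentral members fell (5 and 4 without CDAA 1 and CDAA 3). In the periportal list the Notch ligand Jag1 rose by 0.71 (8 fell and 1 rose when adjusted over the list alone), though Jag1 did not pass without CDAA 1 and CDAA 3 (0.61). The Notch ligand Dll4 fell by 1.31 ± 0.22 (SE, limma adjusted p = 0.00223), and the laminin-like Ntn4 by 1.07 ± 0.22. Of 9 pericentral genes, 4 fell (6 when adjusted over the list alone), led by Wnt9b, a Wnt ligand of central vein endothelium, by 1.08 ± 0.24 (limma adjusted p = 0.00901), and the receptor Kit, by 0.96 ± 0.21. Wnt2 and Rspo3, which also feed hepatocyte Wnt signalling, differed by -0.71 ± 0.26 and -0.39 ± 0.26 and did not pass (limma adjusted p = 0.0832 and 0.362). Wnt2 passed without CDAA 2 (-0.85) or CDAA 4 (-0.87). With the pan-endothelial covariate both changed sign without passing, to 0.28 and 0.63, and Rspo3 also did so without CDAA 1 and CDAA 3 (0.078). Camera adjusted p were 0.000384 for periportal and 0.00672 for pericentral genes, both with an adjusted p = 0.421 with an estimated correlation. The pericentral endothelium list lost its camera call without CDAA 1 and CDAA 3, at a mean of -0.26, and with genes below the median left out (adjusted p = 0.0537), and fry did not call it (adjusted p = 0.0614).

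Some genes of the endothelial lists, and Myc with part of its targets, rose in the isolate against this general fall. Which cells raised them was not tested. Recruited macrophage, cholangiocyte and stellate lists rose in the same pools, with mean changes of 2.86, 2.83 and 1.32. Ednrb, the endothelin B receptor, rose by 2.05 ± 0.18 to 11.35 ± 0.43 (SD, n = 5), and Cd34, a sialomucin of capillary endothelium, by 1.37 ± 0.14 (SE, limma adjusted p = 8.61e-05). Of 19 genes of continuous or capillary endothelium, 6 rose and 2 fell (7 and 3 when adjusted over the list alone), and camera did not call the list (adjusted p = 0.0617). Emcn, endomucin, fell by 0.73 ± 0.23 (limma adjusted p = 0.0485) but did not pass when CDAA 1, CDAA 3 or any Std array was left out, where its change lay between -0.77 and -0.53. Myc (17869_at), a driver of ribosome production and growth, rose by 1.92 ± 0.13, from 6.10 ± 0.20 to 8.02 ± 0.24 (limma adjusted p = 1.12e-05). Of 20 MYC target genes, 7 rose and the cyclin Ccnd2 fell (10 and 1 when adjusted over the list alone); the nucleolar genes Npm1 and Nop58 rose by 0.91 ± 0.22 and 0.72 ± 0.13. With the pan-endothelial covariate none of the 20 MYC targets passed, Npm1 at 1.34 and Nop58 at 0.51, although camera still called the list. The MYC target list had a camera adjusted p of 0.000644, and an adjusted p = 0.197 with an estimated correlation. Pdgfb (18591_at), the growth factor that acts on stellate cells, rose by 0.80 ± 0.16 (limma adjusted p = 0.00487), with values of 7.11 in CDAA 1, 7.25 in CDAA 3 and 6.46 to 6.57 in the other CDAA arrays against 5.98 ± 0.08 in Std. Among 22 endothelial paracrine factors, 6 rose and 7 fell (9 and 9 when adjusted over the list alone), and camera did not call them (adjusted p = 0.757). Bmp6, an iron-regulating ligand like Bmp2, fell by 1.76 ± 0.24, while Igf1 and Igfbp5 rose by 1.25 and 1.09.

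**Figure D2:**
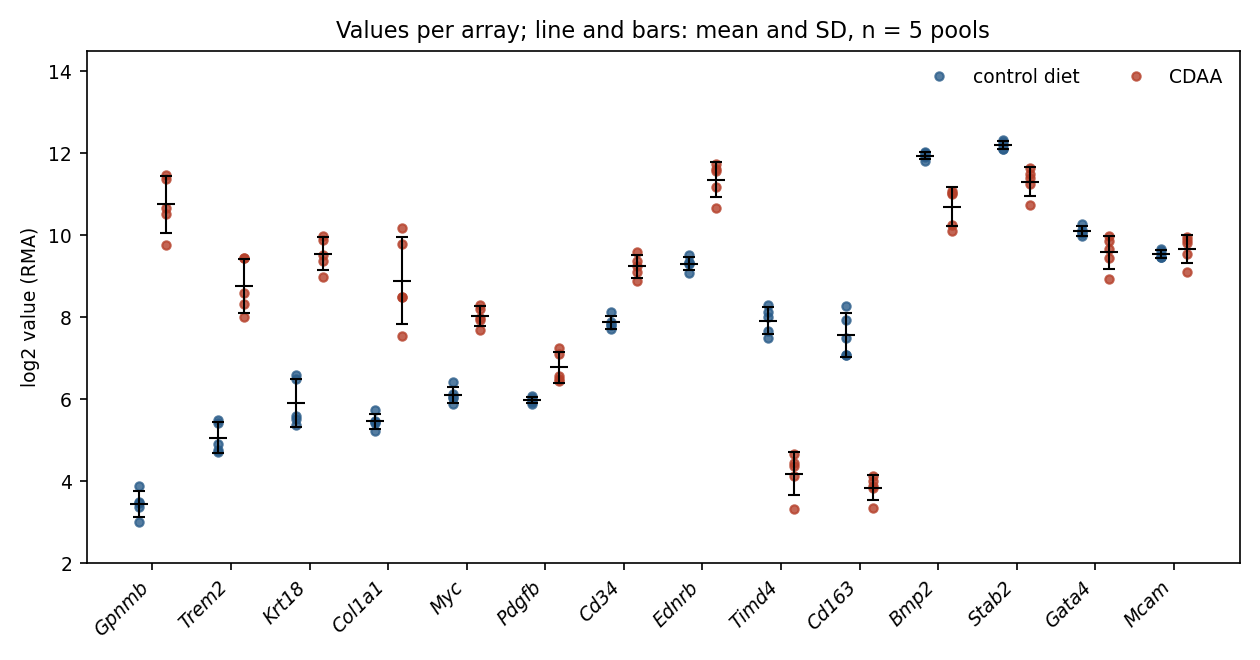
Points are log2 values of 14 genes on each array (y axis), blue for the control diet and red for CDAA, with the mean and SD of 5 pools in black. Gpnmb, Trem2, Krt18, Col1a1, Myc, Pdgfb, Cd34 and Ednrb lie higher with CDAA on all 5 arrays and Timd4, Cd163, Bmp2 and Stab2 lower; Gata4 and Mcam did not pass the test.

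Part of the antigen presentation, chemokine, lipid and cell cycle genes rose with CDAA, whereas more interferon response and cholesterol synthesis genes fell than rose. In the antigen presentation list, 6 of 17 genes rose (7 when adjusted over the list alone), all of the class II pathway, with H2-Eb1 up by 2.58 ± 0.32, H2-Aa by 2.35 ± 0.23 and H2-Ab1 by 2.19 ± 0.20 (SE, limma adjusted p = 5.41e-05). Recruited macrophage markers, with a mean change of 2.86, were highest in CDAA 1 and CDAA 3, as were antigen presentation genes. The class I genes H2-K1 and B2m differed by -0.02 and -0.04. Of 18 leukocyte adhesion and chemokine genes, 9 rose (11, and 1 fallen, when adjusted over the list alone), among them the monocyte chemokine Ccl2, by 1.66 ± 0.29, and the adhesion molecule Vcam1, by 0.77. Without CDAA 1 and CDAA 3 the count was 5. In these arrays the means of this list (8.21 and 7.68) and of the dissociation and immediate early response list (10.49 and 9.99) were the highest of CDAA. In Std the highest arrays of the lists differed, Std 3 (7.15) and Std 1 (9.88). A part of isolation stress in the rise was not tested. Of 14 cholesterol efflux and LXR target genes, 7 rose and Mylip fell, also when adjusted over the list alone, with the cholesterol exporter Abca1 up by 1.46 ± 0.15 (limma adjusted p = 9.28e-05); 3 rose without CDAA 1 and CDAA 3, with a list median of 0.25 against 0.30 and the camera call kept. Mylip, a ubiquitin ligase that acts on the LDL receptor, did not pass without CDAA 1, CDAA 3, CDAA 5 or any single Std array, at changes of -0.61 to -0.42. Of 16 fatty acid uptake and oxidation genes, 7 rose (10, and 3 fallen, when adjusted over the list alone), with lipoprotein lipase, Lpl, up by 2.79 ± 0.31 and the transporter Slc27a1 by 1.89 ± 0.25. In the cell cycle list, 11 of 21 genes rose and Mcm3 fell (16 and 1 when adjusted over the list alone); Mki67 and Top2a rose by 0.95 ± 0.22 and 0.96 ± 0.23, but without CDAA 1 and CDAA 3 both lost their calls, at 0.72 and 0.90, and 1 gene of the list rose, while the list's median stayed at 0.47 against 0.49 and camera still called it. With Std 3 left out as well, 11 genes rose again, and with the pan-endothelial covariate none of the 21 passed, although camera called the list (mean 0.28). Camera adjusted p were 8.13e-05 for antigen presentation, 6.96e-05 for adhesion and chemokines, 0.000143 for efflux, 0.00370 for fatty acids and 4.70e-07 for the cell cycle. None of these 5 lists was called with an estimated correlation (adjusted p = 0.370, 0.111, 0.119, 0.101 and 0.267 with an estimated correlation, in that order).

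Markers of other liver cells moved less evenly. Of 15 hepatocyte markers, 4 rose and 3 fell (6 and 4 when adjusted over the list alone): Alb, Ttr and Fabp1 rose by 1.28 ± 0.20, 1.54 ± 0.22 and 1.78 ± 0.25 (SE, limma adjusted p = 0.00138, 0.000791 and 0.000710), while the pericentral enzyme Cyp2e1 and the urea cycle enzyme Ass1 fell by 1.13 and 1.18. Camera did not call hepatocyte markers (adjusted p = 0.144, and adjusted p = 0.664 with an estimated correlation), but did without CDAA 4 (mean change 0.42) and with the Kupffer cell marker mean as a covariate (0.47). The hepatocyte markers had a mean change of 0.30 with all arrays, 0.027 without CDAA 1 and CDAA 3, and -0.37 with the pan-endothelial covariate. The B and plasma cell list had Jchain, the joining chain of secreted antibodies, up by 2.19 ± 0.43 and Ighm up by 1.13 ± 0.28 among 8 genes, also when adjusted over the list alone (camera adjusted p = 0.201); Ighm did not pass without CDAA 1 and CDAA 3 (0.73). Igkv1-88, a light chain variable segment, rose by 3.81 ± 0.45. No neutrophil marker of 10 passed, over all genes or when adjusted over the list alone, although the list mean was 9.98 in Std 3 against 4.06 to 4.47 in the other Std arrays. Without Std 3, 9 of 10 neutrophil markers rose, with a mean change of 1.59. Among T and NK cell markers, the chemokine Ccl5 rose by 1.15 among 13 genes, also when adjusted over the list alone (camera adjusted p = 0.144). At the preset correlation camera called the list without Std 5, at 0.43, but with all arrays and an estimated correlation it did not (adjusted p = 0.521). Ccl5 did not pass without CDAA 1 (1.10), Std 1 (1.05), Std 2 (0.99) or Std 4 (1.11). In the dendritic cell list, Zbtb46 fell by 0.86 ± 0.17 among 9 genes (2 rose and 1 fell when adjusted over the list alone, with a camera adjusted p = 0.161). The mean change of that list was 0.25, and Zbtb46 did not pass with the pan-endothelial covariate. Prox1 and Pdpn, of the lymphatic and mesothelial list, rose by 1.91 ± 0.23 and 0.98 ± 0.13 among 6 genes, also when adjusted over the list alone, and the list's median of -0.03 had the opposite sign to its mean of 0.34 (camera adjusted p = 0.201). None of 7 erythroid and platelet markers passed, over all genes or when adjusted over the list alone (camera adjusted p = 0.757). Of 4 measured sex-linked transcripts, Xist rose by 0.90 ± 0.15 and the Y-linked genes stayed between -0.16 and 0.12; the list was too short for camera.

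**Figure D3:**
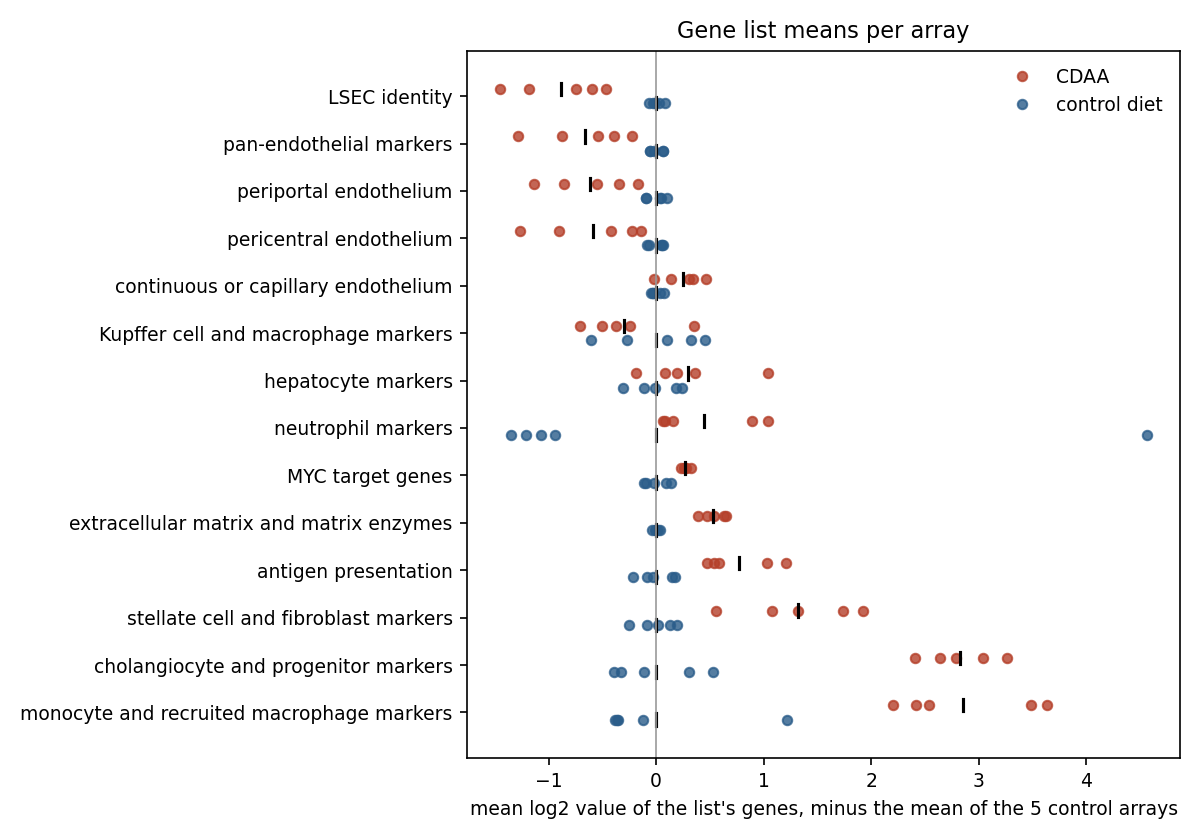
Each point is the mean log2 value of a gene list on an array minus the mean of the 5 Std arrays (x axis), red for CDAA and blue for the control diet; black ticks are means of 5 pools. The recruited macrophage, cholangiocyte and stellate lists lie to the right in all CDAA arrays, with mean changes of 2.86, 2.83 and 1.32, the LSEC and pan-endothelial lists lie to the left (-0.89 and -0.67), and Std 3 stands apart for neutrophil markers.

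Signalling and stress lists held genes that moved in both directions. Klf2, a flow-induced transcription factor, fell by 0.58 ± 0.11 (SE, limma adjusted p = 0.00346); the shear stress list had 2 genes risen and 2 fallen of 12, also when adjusted over the list alone, with a median of -0.10, a mean of 0.01 and a camera adjusted p of 0.750. In the Notch list, 4 of 13 genes fell, Notch1 by 0.75 ± 0.14, and 1 rose (5 and 2 when adjusted over the list alone; camera adjusted p = 0.275). Of 13 TGF-beta and BMP response genes, 4 rose, Ltbp2 by 1.40 ± 0.22 and Id2 by 0.80 ± 0.17, and 3 fell, among them the inhibitors Smad6 and Smad7 by 0.69 and 0.51 (5 and 3 when adjusted over the list alone; camera adjusted p = 0.317). Smad6 did not pass without CDAA 1 (-0.60), Std 1 (-0.68) or Std 4 (-0.64), nor Smad7 without Std 4 (-0.48). The hypoxia and glycolysis list had 4 genes risen and 2 fallen of 17, also when adjusted over the list alone (camera adjusted p = 0.217), with Vegfa and the glucose transporter Slc2a1 both up by 1.36 and Adm down by 1.36 ± 0.24. In the interferon response list, 3 of 18 genes fell, Cmpk2 by 0.69 ± 0.13, and 1 rose (4 and 1 when adjusted over the list alone; camera adjusted p = 0.161). Of 14 genes of endoplasmic reticulum and amino acid stress, 1 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.746). Of 16 cholesterol synthesis genes, 4 fell, Mvk by 0.68 ± 0.16 (6 fell and 1 rose when adjusted over the list alone; camera adjusted p = 0.123). Without CDAA 1 and CDAA 3, the risen and fallen genes numbered 0 and 1 for shear stress, 0 and 3 for Notch, 3 and 0 for TGF-beta and BMP, 0 and 2 for interferon and 0 and 0 for endoplasmic reticulum stress.

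A few list calls turned on single arrays. The NRF2 and oxidative stress list, with 3 genes risen and 1 fallen of 11 (5 and 1 when adjusted over the list alone), had a camera adjusted p of 0.0462 and an adjusted p = 0.421 with an estimated correlation; its mean change of 0.25 was not called without CDAA 1 (0.19), CDAA 3 (0.20), Std 1 (0.23), Std 2 (0.25) or Std 5 (0.24), and none of its genes passed without CDAA 1 and CDAA 3. In the dissociation and immediate early response list, which marks stress during isolation, Atf3 and Nr4a1 rose by 2.67 ± 0.57 and 1.30 ± 0.28 among 14 genes, also when adjusted over the list alone (limma adjusted p = 0.00747 and 0.00856). Its camera adjusted p was 0.0137, with an adjusted p = 0.545 with an estimated correlation, and the mean change of 0.66 was not called without CDAA 1 (0.39), CDAA 3 (0.51), Std 2 (0.44) or Std 5 (0.51). The cholesterol synthesis list, at -0.16 with all arrays, passed under 7 of 26 other settings, among them without CDAA 1 (-0.22), CDAA 3 (-0.19) or both (-0.29, with 6 of 16 genes fallen). The continuous or capillary endothelium list, at 0.25, passed under 10 of 26, among them without CDAA 1 (0.27), CDAA 3 (0.31), both (0.37), Std 1 (0.25) or Std 3 (0.26). Neither was called with an estimated correlation (adjusted p = 0.521 for cholesterol synthesis and adjusted p = 0.421 for capillary endothelium, with an estimated correlation).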

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

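The 3 tests of the LSEC pattern and the 2 tests of the macrophage pattern were chosen only after the result was seen, whereas the 2 neutrophil tests and both counts over splits were set before theirs. In 352 groups of 5 values, 16 had an array far from the other 4, where chance gives about 17.6 (1 in 20). The values below are the gap to the nearest array as a share of the group's range.

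Neutrophil markers stood far apart in Std 3 (share 0.931; list mean 9.98 against 4.06 to 4.47), with S100a9, a granule protein of neutrophils (0.903; 9.99 against 4.44 to 4.98), and Cxcl2, a neutrophil chemokine (0.733; 7.99 against 3.45 to 4.66). A second neutrophil list, not used to see the pattern, had 10 of 11 genes over 1 log2 above the highest other Std array, with Lcn2 at 12.90 against 6.69 and Mmp8 at 10.44 against 3.70, a value below the array median of 3.89. An array distorted across all genes is argued against by the ratio of 11.1, since 400 genes lay over 1 log2 above the mean of the other Std arrays and 36 below. Neutrophils in that pool may account for these values, although CD146 beads were meant to leave such cells out. Whether they came from the mice or from the isolation cannot be known from 1 pool, and no reason for their presence was tested.

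LSEC identity genes were lower with CDAA. An equal loss of all endothelial transcripts is argued against by the list mean, which fell by 0.223 more than the pan-endothelial mean (difference -0.223, exact permutation p = 0.00794, the smallest possible, lower in 5 of 5 CDAA arrays). A lower share of endothelial cells need not lower both lists equally, because some list genes are expressed by more than 1 cell type. The difference therefore does not argue against such a lower share. CDAA 1 and CDAA 3, the lowest in endothelial markers, did not carry the fall alone, since 14 of 20 genes still fell without them (median -0.58), and a lower endothelial share that raised all other cell types alike is argued against by list changes 3.15 apart, the highest (recruited macrophages) against the lowest (Kupffer cells) of 11 lists. That gap was the widest over all arrangements of the arrays, each with its own highest and lowest list (exact permutation p = 0.00794), as was the gap of 2.95 among the 10 lists without the Kupffer list, whose members moved both ways. The lowest of those 10 was the erythroid and platelet list, at 3.88 in Std, near the array median of 3.89, where a rise may not show. Hepatocyte markers, at 7.06 in Std, had a mean change of 0.30. Rises that differ between cell types are not addressed by these gaps. With the pan-endothelial covariate the LSEC list's median change went from -0.86 (median SE 0.179) to -0.18 (0.143) and its fallen genes from 17 to 1, because the changes shrank and not because their errors grew, while camera still called the list (mean -0.25). That call is at the preset correlation. With an estimated correlation, run without covariates only, camera did not call the LSEC list (adjusted p = 0.303). Most of the fall of LSEC genes could thus be shared with endothelial genes in general, so RNA of other cell types and the diet itself both stay open.

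The recruited macrophage list rose and the Kupffer cell list, with members moving both ways, did not. More macrophages of the same make-up would have moved both lists alike, and they lay 3.15 apart (exact permutation p = 0.00794), a difference that had been seen before it was tested. A set of 6 general macrophage genes, all also in the Kupffer list, differed by a mean of 0.545 (exact permutation p = 0.135) and none passed in limma, but the set leaves out Cd68, which rose by 1.38. A different carry-over of macrophages through bead isolation cannot be told apart from the diet, since each pool was isolated once. A change in the macrophages of the liver with the diet may underlie the pattern and stays untested.

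Of the 100 splits, 1 called as many genes as the diets, namely the real one with 4106, and the highest other called 1. No other split drawn thus reached that count. Every other split mixed the diets, so the diet difference added to the spread within its groups and lowered its count. The comparison cannot tell the diet from a batch or isolation difference that ran with it. For gene lists with the preset correlation, 15 of the 100 splits called as many lists (real value 16, highest other 19), so chance cannot be excluded for that count. The split with 19 lists set CDAA 1, 2, 3, 5 and Std 3 against the others, and 93 of the other 99 called at least 1 list. Each of these splits kept part of the diet difference. Their calls therefore cannot tell that difference from a structure shared by genes of a list across arrays.

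In CDAA, the leukocyte adhesion and chemokine list was high in CDAA 1 (0.751; 8.21 against 7.51 to 7.68). In Std, the recruited macrophage list was high in Std 3 (0.839; 6.02 against 4.42 to 4.68), the fatty acid list in Std 2 (0.911; 7.86 against 7.70 to 7.72) and the T and NK cell list in Std 5 (0.744; 5.63 against 4.42 to 4.73). Single genes in CDAA were Cxcl13, low in CDAA 2 (0.837; 3.59), Klf2, low in CDAA 5 (0.867; 8.66), and Vsig4, high in CDAA 3 (0.848; 9.62). In Std they were Igkv1-88 in Std 1 (0.802; 4.45), Atf3 in Std 1 (0.772; 8.48), Fabp5 in Std 2 (0.824; 6.03), Slc2a1 in Std 3 (0.726; 7.63) and Ccl5 in Std 5 (0.770; 8.92), all high, and Ltbp2, low in Std 2 (0.813; 4.19). Among the 723 probe sets without a gene name here, which no comparison used, 53 rose and 66 fell with CDAA.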

How the results depend on the processing

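Tests without CDAA 1 and CDAA 3, without these and Std 3, and with the pan-endothelial or neutrophil covariate were chosen only after the result was seen. Of the 127 named genes that changed, 108 stayed past the threshold in the same direction without any single array, and the numbers that did so elsewhere were 103 without CDAA 1 and CDAA 3, 109 without these and Std 3, 109 with the hepatocyte covariate, 59 with treat and 41 with the pan-endothelial covariate. The planned block, normalizations, Kupffer covariate, trend and weights cost at most 4 named calls each. Leaving out 1 array gave 2956 (Std 4) to 4572 (CDAA 4) genes. With treat, 452 genes passed (357 risen, 95 fallen), fewer by construction, since changes under 0.5 are not counted. With the hepatocyte covariate, 1476 genes fell. Without CDAA 1 and CDAA 3, 2612 genes passed, of which 1307 fell; with Std 3 also left out, 2689 passed and 1288 fell. These fits have fewer arrays. With the pan-endothelial covariate, 363 passed (248 risen, 115 fallen), 332 of them among the 4106; that covariate moves with the diet. Among results called with all arrays, its estimates changed sign for Emcn (0.13), Col15a1 (-0.044), Dll1 (0.014), Mylip (0.069), pericentral endothelium (0.15), NRF2 and oxidative stress (-0.048) and dissociation and immediate early response (-0.13), none past the threshold. Results not called with all arrays also turned, among them Gata4 (0.11), Lyve1 (0.23), Wnt2 (0.28), Rspo3 (0.63), C1qa (-0.25), endothelial paracrine factors (0.19), hepatocyte markers (-0.37) and neutrophil markers (-0.45), again without passing. The cause was not tested. With an estimated correlation, camera called 0 lists (0 risen, 0 fallen, smallest adjusted p 0.0622), and fry called 17. Fry kept, for example, LSEC identity (fry adjusted p = 0.00591) and recruited macrophages (0.000156). Besides the pericentral list it did not call NRF2 (0.114) or immediate early response (0.305). Fry newly called capillary endothelium (0.0232), interferon response (0.0232), TGF-beta and BMP response (0.0221) and lymphatic and mesothelial markers (0.0456). With the replicate block, 4178 genes passed (1893 risen, 2285 fallen; 3683 shared) and 16 lists. Within lists, the block raised the risen genes from 2 to 7 of 14 for dissociation and immediate early response and from 1 to 4 of 11 for Kupffer cell and macrophage markers. No label ties same-numbered arrays together, and not every pair was above 0.1: their deviations correlated at 0.016, 0.138, 0.231, 0.249 and 0.095 across genes, and 6 of 10 arrays correlated best with their own number. Quantile normalization again and median centring (4105 genes each) and the mean of a gene's probe sets moved almost nothing, so they test little.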

Other observations

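All of the gene families and the pancreatic list here, and the tests on them, were chosen only after the result was seen. Gamma protocadherins, adhesion molecules encoded in one cluster with shared exons, had no member that rose and 12 of 22 that fell (9 without CDAA 1 and CDAA 3), against 9.13% of all genes (Fisher's exact test adjusted over the 10 families, p = 2.93e-07). Pcdhgb5 fell by 1.63 and Pcdhga10 by 1.10. Since these transcripts share sequence, their probe sets are not independent. Of 23 claudins, the proteins of tight junctions, 6 rose and 1 fell, with the epithelial Cldn4 and Cldn3 up by 2.92 and 2.61, whereas Cldn5, of endothelial junctions, fell by 0.98. Of 23 cathepsins, lysosomal proteases, 7 rose and 1 fell, with Ctss up by 1.66 (4 rose without CDAA 1 and CDAA 3). Of 21 Ms4a genes, 6 rose and 1 fell, with Ms4a7, a macrophage gene, up by 3.00 (4 rose without CDAA 1 and CDAA 3). Among 20 semaphorins 5 rose and 5 fell, with changes of 1.84 for Sema3c and -1.73 for Sema3d. With the pan-endothelial mean as a covariate, Pcdhgb5, Pcdhga10, Cldn5, Ctss and Sema3d did not pass. Cldn4, Cldn3, Ms4a7 and Sema3c kept their calls with it.

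Immunoglobulin genes had 18 of 215 members risen and none fallen (9 risen without CDAA 1 and CDAA 3), with Igha, the heavy chain of IgA, up by 3.40 and Igkc, the kappa constant chain, up by 2.11. The share that rose, 8.37%, was close to the 7.49% of all genes. The absence of falls differed from the 9.13% of all genes that fell (Fisher's exact test adjusted over the 10 families, p = 1.26e-08). Some members had Std means below the array median of 3.89, where a fall may not show, such as Igkv1-88 (3.63) and Ighv4-1 (2.70). Others, such as Igha (5.83) and Igkc (8.86), lay above it. Falls were also rare among olfactory receptors (0.643%, Fisher's exact test adjusted over the 10 families, p = 4.70e-35). Of 44 collagens 10 rose and 4 fell, of 50 keratins 6 rose and 2 fell, and of 22 subunits of the vacuolar proton pump 4 rose and 1 fell (8 and 3, 5 and 2, and 1 and 2 without CDAA 1 and CDAA 3). The 1088 olfactory receptors had 5 risen and 7 fallen (3 and 2 without these arrays). Gata6, a relative of Gata4, rose by 1.64. With the pan-endothelial mean as a covariate Gata6 and Igkc did not pass, whereas Igha kept its call. Rises were over-represented by Fisher's exact test among claudins (adjusted p = 0.0117), cathepsins and collagens (both 0.00426), Ms4a genes (0.00892) and semaphorins (0.0235), and not among immunoglobulins (0.602), keratins (0.340) or proton pump subunits (0.111). Falls among semaphorins, as many as rises, had an adjusted p of 0.0765 by the same test. The Fisher tests treat genes as independent, which genes measured on the same arrays are not. Adjustment over the 10 families does not correct for their choice after the changes were seen, so these p-values describe the families and lend no support.

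Genes of pancreatic acinar cells, such as Ctrb1 and Cela2a, were high in some pools of both diets. The list mean was 9.76 in CDAA 3, 8.16 in CDAA 4, 6.81 in CDAA 1 and 7.14 in Std 4, against 4.55 in CDAA 2, 3.84 in CDAA 5 and 3.78 to 3.92 in the other Std arrays. No gene of that list passed in the comparison by diet (limma, smallest adjusted p 0.116). Relations of single endothelial genes to marker means within a diet were also computed and then set aside, because 5 arrays per diet are too few for a correlation.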
